A study of Homo sapiens with 12 samples.

How the data were processed

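The series holds 12 libraries from 2 human melanoma lines. A375 is a line with an activated BRAF gene. The other line is A375 made to overexpress MIR211, the gene of the microRNA miR-211, and is called the MIR211 line here. RNA-seq was done on total RNA, with 2 libraries per line labelled a and b. In BRIC-seq, cells are fed 5-bromouridine (BrU), the label is chased with unlabelled nucleoside, and BrU-containing RNA is pulled down with an antibody, so that RNA made before the chase is followed as it disappears. There were 8 BRIC-seq libraries, 1 per line at 0, 1, 3 and 6 h. Per the labels' protocols, BrU was given for 24 h and all libraries were made with a stranded total RNA kit.

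The authors deposited 2 tables of read counts per gene, with no normalization, as whole numbers that sum to a different total in each library. One table holds the RNA-seq libraries and the other the BRIC-seq libraries. Reads were aligned with HISAT2 2.1.0, per the submitters' processing notes, which also name StringTie. The series' design text says that StringTie quantified the reads and that the authors tested them with DESeq2. The notes give the genome build as hg19 and the design text gives hg38, so no coordinate was taken from the deposited tables. The strand setting and the treatment of multi-mapping reads are not given in the sources used here. Counts of antisense genes, overlapping genes, pseudogenes and near-identical paralogs are therefore uncertain.

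Both tables list 60675 Ensembl gene IDs. Of these, 41209 (67.9%) were given a symbol from GENCODE 44 (hg38), and coordinates printed here are 1-based positions in that annotation. The BRIC-seq table holds 1 further row that names no gene. It was left out of library sizes and tests, and its share of the counts lay between 0.000108% and 0.00122% of a library. All deposited columns were used.

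Counts were tested with edgeR 4.0.16 (quasi-likelihood fit and F test, R 4.3.3), with TMM scaling and Benjamini-Hochberg adjustment within each comparison. An adjusted p under 0.05 counted as passing. Genes were kept by filterByExpr by line (minimum count 10, minimum total 15). The RNA-seq comparison used the 4 RNA-seq libraries with the line as the only term, which left 2 residual degrees of freedom. All BRIC-seq results came from the 8 BRIC-seq libraries. The mean slope is the coefficient of hours with the line as a covariate (5 residual degrees of freedom). The slope of each line and their difference, MIR211 line minus A375, came from a fit with a line and a slope per line (4 residual degrees of freedom). The line difference is the line coefficient with each time matched (3 residual degrees of freedom), where the 4 times stand in for replicates. With 1 library per line and time, the spread is that about the fitted line or the matched times. Standard errors are the size of the log2 value divided by the square root of F. Slopes are in log2 per hour relative to the scaled total of labelled RNA. They rank transcripts and are not absolute decay rates, since that total itself shrinks over a chase.

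The labels do not say that the libraries of a line came from separate cultures, so p-values measure the spread between these samples, which may be technical. CPM values use TMM-scaled library sizes. Intervals are exact (Poisson for counts, conditional binomial for ratios, Clopper-Pearson for shares) at 95% and cover counting error only. A fold against a line with a count of 0 in all its libraries is a lower bound, set with a floor of 3 counts over the group.

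The genes named were chosen by a rule. In RNA-seq it took the 10 largest rises and 10 largest falls among passing genes with a symbol, an average log2 CPM of at least 3 and both libraries of one line above both of the other. In BRIC-seq it took the 10 most positive and 10 most negative passing coefficients at an average log2 CPM of at least 5, or, where none passed, the 5 of each sign with the smallest p. MIR211, its host gene TRPM1, DUSP3 and the reported miR-211 targets were always included, as were up to 4 members of each list with the smallest p. Genes named outside this rule are marked as chosen after their values were seen.

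The 24 gene lists were reported miR-211 targets, miR-204 and miR-211 family targets, ERK output, melanocyte lineage, invasive state, TGF-beta response, proliferation, immediate early genes, glycolysis, ribosomal proteins, mitochondrially encoded mRNAs, nuclear OXPHOS, replication-dependent histones, SNHG and other lncRNAs, ZNF genes, UPR and ATF4, cholesterol synthesis, p53 targets, interferon response, hypoxia, and markers of keratinocytes, fibroblasts, leukocytes and endothelium. The lists were written from general knowledge, and some reported targets were described in melanoma lines, so that the reported target list is not fully independent of such data. Lists with at least 3 measured genes were tested with camera in limma 3.58.1 (preset correlation 0.01), again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Camera compares a list with all other genes, whereas fry asks whether its genes move one way on balance.

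Sites for miR-211 were searched in the longest annotated 3' UTR of 19238 genes (Python 3.11.15). The 7mer AAAGGGA pairs with the seed, and the 8mer has a further A at its end. The shift of genes with the 7mer was ranked among the 35 7mers of the same base composition, with the genes resampled for an interval of the rank. A gene with no annotated 3' UTR was not searched.

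The designs, lists, naming rule and alternatives were fixed before the data were examined, apart from those marked as chosen afterwards. The alternatives were DESeq2 1.42.0, RLE factors, total counts, no filter, a mean CPM of at least 5, a fold threshold, each library left out, the letters a and b as a block, glycolytic mRNAs held constant (7 genes), the rank of time, time as a shared factor and the 0 h pair left out. Scaling to the row without a gene and leaving out mitochondrially encoded genes were chosen after seeing the data. The tests were tested on simulated counts with 100 genes changed at each size and the same dispersion for all genes. For RNA-seq (18850 genes), 10% were recovered at a log2 change of 1 and 100% at 3. For a change of these sizes over the 6 h chase, the mean slope (13001 genes) recovered 16% and 100%, and the slope difference (13002 genes) 1% and 42%. The line difference (12996 genes) recovered 76% and 100%.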

Results

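A375 melanoma cells were compared with the MIR211 line, which is A375 made to overexpress MIR211. Steady-state RNA was measured in 2 RNA-seq libraries per line, with 20.8 and 28.4 M counts in A375 and 34.1 and 30.5 M in the MIR211 line. The decay of BrU-labelled RNA was followed by BRIC-seq with 1 library per line at 0, 1, 3 and 6 h of chase. These held 2.67, 3.95, 6.81 and 7.28 M counts in A375 and 2.78, 4.53, 6.26 and 6.66 M in the MIR211 line, so the later times were counted more deeply. The comparisons address which transcripts differ in level between the lines and which decay at a different rate. With only these 2 lines, an effect of miR-211 cannot be told apart from other differences between them.

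MIR211, whose hairpin lies within an intron of TRPM1, was seen in every library of the MIR211 line and in none of A375. In RNA-seq its counts (ENSG00000207702, chromosome 15, 31065032 to 31065141) were 0 and 0 in A375 and 36 and 18 in the MIR211 line, at least 13.6-fold higher. In BRIC-seq they were 0 at all 4 times in A375 and 9, 11, 2 and 3 at 0, 1, 3 and 6 h in the MIR211 line, at least 9.12-fold higher. These libraries count RNA from the gene locus, and mature miR-211 was not measured. The RNA-seq test of MIR211 did not pass (edgeR quasi-likelihood test, adjusted p = 0.125, average log2 CPM -0.97), whereas DESeq2 called it. TRPM1 had 3 and 4 RNA-seq counts in A375 and 4 and 1 in the MIR211 line, which is too few for a comparison.

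In RNA-seq, IL24, TGM2, LAMA2 and IZUMO3 were among the genes that rose in the MIR211 line. IL24, a cytokine of the interleukin-10 family (ENSG00000162892, chromosome 1, 206897443 to 206904139), rose from 27.1 ± 11.7 to 609 ± 171 CPM (SD, n = 2 per line), a log2 change of 4.49 with a standard error of 0.44 (edgeR quasi-likelihood test, adjusted p = 0.0495). TGM2, the tissue transglutaminase that crosslinks matrix proteins, rose from 7.15 ± 2.39 to 128 ± 39.8 CPM. The basement membrane chain LAMA2 rose from 2.96 ± 0.496 to 38.6 ± 5.96 CPM, and the protocadherin FAT3 from 2.44 ± 0.934 to 89.9 ± 6.12 CPM. IZUMO3, a member of a family of sperm membrane proteins, rose most among passing genes with an average log2 CPM of at least 3, from 0.615 ± 0.0335 to 107 ± 4.72 CPM (log2 7.43, SE 0.23, adjusted p = 0.0139). It was followed by the small secreted peptide FDCSP (log2 6.33, SE 0.49) and the lipid transporter ABCA8 (log2 5.36, SE 0.30). VCX3B and VCX on the X chromosome (log2 4.48 and 4.25) and the tubulin pseudogene TUBAP13 (log2 4.68) rose too. They belong to near-identical families, so their reads are uncertain.

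Lower in the MIR211 line were MITF, the master transcription factor of the melanocyte lineage, and the apoptosis inhibitor BIRC7. MITF fell from 248 ± 6.22 to 43.9 ± 7.23 CPM (log2 -2.50, SE 0.20, n = 2 per line, edgeR adjusted p = 0.0448). BIRC7 fell from 31.6 ± 0.779 to 0.109 ± 0.029 CPM, and the collagen chain COL11A1 from 308 ± 2.95 to 1.26 ± 0.869 CPM. UTS2, which encodes the vasoactive peptide urotensin, fell from 275 ± 39.1 to 7.85 ± 1.35 CPM, and GLDC, the decarboxylase of the glycine cleavage system, from 261 ± 10.7 to 14.1 ± 2.09 CPM. The hair follicle keratin KRT75 (log2 -5.42) and the proton pump subunit ATP6V0D2 (log2 -4.96) also fell. Of the noncoding RNAs, LINC00698 had 1710 counts in A375 and 0 in the MIR211 line, at least 753-fold lower. The pseudogene SMG1P2 had 860 and 0, at least 379-fold lower, with uncertain reads. The antisense gene SYT9-AS1 (log2 -5.85) and the readthrough gene ANKHD1-EIF4EBP3 (log2 -4.28) fell as well, with reads that are uncertain because other genes overlap them.

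Across 19258 genes tested in RNA-seq, 73 passed (33 higher and 40 lower in the MIR211 line), while 2107 had an unadjusted p under the same threshold. This count rested on both libraries of each line. With the A375 library a, the A375 library b or the MIR211 library a left out, 0 genes passed by edgeR, and with the MIR211 library b left out 15 passed. DESeq2 on all 4 libraries called 748.

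PDK4, the kinase that holds back pyruvate oxidation and a reported miR-211 target, fell from 59.1 ± 3.19 to 13.5 ± 0.157 CPM in RNA-seq (log2 -2.13, SE 0.17, n = 2 per line, edgeR adjusted p = 0.0441). It was the only one of 14 reported targets to pass, and also the only one adjusted over the list alone. The phosphatase DUSP3 (ENSG00000108861, chromosome 17, 43766125 to 43778977), which has 2 seed 7mers in its 3' UTR, went from 69.8 ± 2.82 to 12.7 ± 3.3 CPM (log2 -2.46, SE 0.25) and just missed the threshold with adjusted p = 0.0533. It passed with DESeq2, with no count filter and with a mean CPM of at least 5. The growth factor binding protein IGFBP5 (log2 -2.64, SE 0.71) and the endoplasmic reticulum protein EDEM1 (log2 -0.97, SE 0.29) did not pass with adjusted p of 0.27 and 0.325. NUAK1 (log2 1.39, SE 0.36) and TGFBR2 (log2 0.64, SE 0.26) lay above 0 without passing, and KCNMA1, IGF2R, SOX11 and SERINC3 lay between -0.98 and -0.32. POU3F2, NFAT5, RAB22A, AP1S2 and DUSP6 differed by less than 0.1 on the log2 scale, each within its standard error. Seed 7mers are also present in targets that did not fall, with 4 in RAB22A, 3 in NUAK1 and 2 in POU3F2, while PDK4 and IGFBP5 have 1 each. As a list the reported targets did not pass by camera (adjusted p = 0.0605). None of 15 miR-204 and miR-211 family targets passed (camera adjusted p = 0.254).

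**Figure D1:**
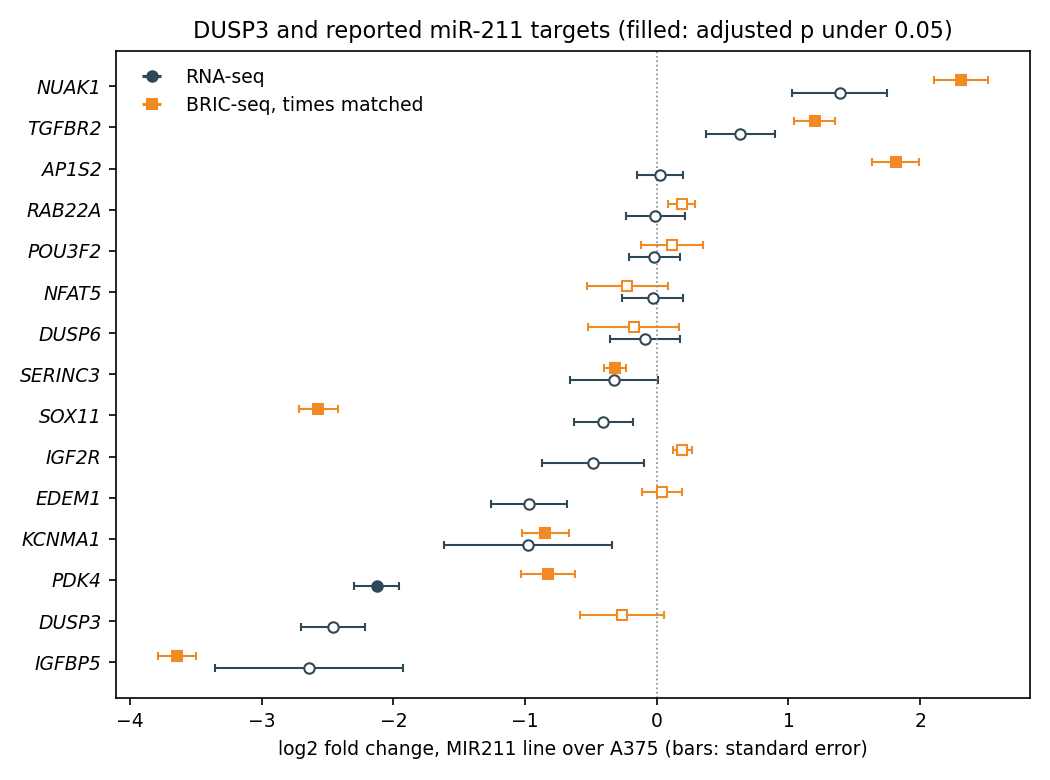
Log2 fold change of DUSP3 and the 14 reported miR-211 targets in the MIR211 line over A375, by RNA-seq (2 libraries per line) and by BRIC-seq with the 4 times matched, where bars are standard errors and filled symbols passed the threshold. In RNA-seq the lowest values are those of IGFBP5 (-2.64), DUSP3 (-2.46) and PDK4 (-2.13), and in BRIC-seq those of IGFBP5 (-3.64) and SOX11 (-2.57).

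Among melanocyte genes only MITF of 14 measured passed in RNA-seq, and adjusted over the list alone 3 rose and 3 fell. BCL2A1 (log2 2.24), the endothelin receptor EDNRB (log2 1.73) and CDK2 (log2 0.85) rose, while MITF, the melanosome transport protein RAB27A (log2 -1.08) and the fibril protein PMEL (log2 -1.51) fell. Of 22 genes of the invasive state 0 passed among all genes by edgeR. Adjusted over the list alone 2 did, the ligand WNT5A (log2 2.20, SE 0.25) and the gelatinase MMP2 (log2 1.38, SE 0.17). The invasive list was high against other genes by camera (adjusted p = 0.00932), with 17 of 22 values above 0. That call was lost with an adjusted p = 0.919 with an estimated correlation. Interferon response genes had 23 of 27 values above 0 with a median of 0.49 and no member that passed. Camera called the list (adjusted p = 0.00079, and adjusted p = 0.919 with an estimated correlation). All 22 genes of the UPR and ATF4 list had values under 0 with a median of -0.38, and 20 of 28 immediate early genes lay above 0. The A375 libraries lay far apart for some UPR and ATF4 genes, as for ASNS, chosen after its values were seen (184 ± 141 CPM in A375 and 112 ± 66.3 CPM in the MIR211 line, n = 2). Both lists were called by camera (adjusted p = 0.023 each, and adjusted p = 0.919 with an estimated correlation for both). The transcription factor KLF2 (log2 2.12) rose adjusted over the immediate early list alone. By fry none of the 21 lists tested passed.

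The remaining RNA-seq lists had few members that passed. Adjusted over the list alone, the ERK output gene EPHA2 rose (log2 1.44), and 2 of 18 TGF-beta response genes fell, among them the matrix protein LTBP2 (log2 -2.83). Of the p53 targets GDF15 (log2 -4.16) and PHLDA3 (log2 -1.22) fell while CDKN1A (log2 1.26) rose, also adjusted over the list alone. As a list the p53 targets had 15 of 20 values above 0 in RNA-seq with a median of 0.36, which camera did not call (adjusted p = 0.222). The ribosomal protein RPL29 (log2 -1.50) fell adjusted over its list alone. ZNF286A (log2 -2.11) was the only one of 504 ZNF genes to pass among all genes, with 0 passing adjusted over the list alone. Of 30 proliferation genes, 17 glycolysis genes, 13 mitochondrially encoded mRNAs, 30 nuclear OXPHOS genes, 46 replication-dependent histones, 22 SNHG and other lncRNAs, 18 cholesterol synthesis genes and 15 hypoxia genes, 0 passed either way by edgeR. Median, mean and camera direction differed in sign for the histones (0.10, -0.03 and up). For the melanocyte lineage the median of -0.02 and mean of -0.06 lay under 0 while camera pointed up (adjusted p = 0.93). Markers of other cell types were sparse. Of the fibroblast markers, PDGFRB (log2 1.45), LUM (log2 1.30) and DCN (0.0737 to 1.28 CPM) rose and COL1A2 (34.1 ± 23.9 to 0.377 ± 0.199 CPM, n = 2) fell adjusted over the list alone, while 0 of 5 passed among all genes. The keratinocyte marker KRT14 was at 0 in A375 and 0.452 ± 0.139 CPM in the MIR211 line, a rise adjusted over its list alone. Neither the leukocyte marker LYZ (log2 -0.94) nor the endothelial markers KDR (log2 1.05) and VWF (log2 0.41) passed.

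Over the chase, GAPDH rose and MYC and DUSP4 fell within the labelled RNA of both lines. GAPDH, a glycolytic enzyme, went from 264 to 2461 CPM between 0 and 6 h in A375 and from 372 to 3554 CPM in the MIR211 line, a mean slope of 0.55 log2 per hour with a standard error of 0.02 (n = 8 libraries, edgeR adjusted p = 3.22e-06). MYC, a growth-promoting transcription factor with an unstable message, fell from 15.9 to 0.603 CPM in A375 and from 14.9 to 0.735 CPM in the MIR211 line (mean slope -0.85, SE 0.09). Both 6 h values of MYC stand for 3 counts. DUSP4, a phosphatase that feeds back on ERK, fell by 0.79 log2 per hour (SE 0.10). These directions are relative to the scaled total of labelled RNA. The rise of GAPDH turned into a slope of -0.13 per hour when the libraries were scaled to the row without a gene, whereas DUSP4 fell under each scaling.

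Among passing genes with a symbol and an average log2 CPM of at least 5, the 10 steepest rises in the mean slope were DDOST, a subunit of the oligosaccharyltransferase (0.67, SE 0.05), the actin gene ACTB (0.57, SE 0.11), the pseudogene GAPDHP1 (0.56, with reads shared with GAPDH), ITM2A, GAPDH, the lysosomal protein LAPTM4B, LAMA2, SH3BGRL, the secreted peroxidase GPX3 and the glycolytic enzyme TPI1 (0.53). LAPTM4B no longer passed without the 0 h (0.42) or the 6 h (0.41) library of the MIR211 line. Under the same limits the 10 steepest falls were BTG1, an antiproliferative gene (-0.85, SE 0.19), ZNF281 (-0.83), KIAA0232 (-0.80), TENT5A (-0.80), DUSP4, FLRT3 (-0.79), the ubiquitin ligase TOPORS (-0.78), the transcription factor PLAG1 (-0.77), PPP1R15B, which recruits a phosphatase to the translation factor eIF2 (-0.75), and IRF2BP2 (-0.74). For BTG1 and LAPTM4B the mean may describe neither line. DESeq2 called their slope differences, MIR211 line minus A375, and edgeR did not. These were 1.48 (SE 0.305, DESeq2 adjusted p = 0.00395) and 0.71 (SE 0.157, DESeq2 adjusted p = 0.0126). All 10 rises turned negative when scaled to the row without a gene, and all but DDOST and GAPDH no longer passed with glycolytic mRNAs held constant. The row held 3 counts at 0 h in each line and had a slope of 0.647 log2 per hour (SE 0.048). Genes with slopes under that of the row turn negative by construction, and the sign of DDOST, whose slope is close to it, is uncertain.

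Of 13703 genes, 8815 had a mean slope that passed, 4100 rising and 4715 falling (53.5% falling). The split depended on the scaling. Total counts moved the median slope by -0.166 (79.7% falling of 9115 genes), and glycolytic mRNAs held constant moved it by -0.464 (99.9% of 11841). The row without a gene moved it by -0.679 (100% of 13394, with 1 rising). In A375 alone 6465 genes passed (3149 rising, 3316 falling) and in the MIR211 line 5877 (3002 rising, 2875 falling). The slopes of both lines correlated across genes (Pearson 0.803, Spearman 0.891, genes not being independent replicates). Both lines called 2302 genes falling and 2545 rising, where independent lists would share 695.7 and 689.9, and 4 genes had opposite calls. Without its 6 h library the A375 slope called 0 genes and the MIR211 line slope called 0 genes, and without the 1 h library of the same line they called 4308 and 3914.

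Zinc finger (ZNF) genes, most of which encode transcription factors, fell as a group within labelled RNA, with 337 of 395 falling and 4 rising (340 and 4 adjusted over the list alone), under each scaling tried. ZNF860 (-0.56), ZNF160 (-0.51) and ZNF772 (-0.63) were among them. Camera called the list (adjusted p = 8.76e-19, and adjusted p = 0.376 with an estimated correlation). All 17 immediate early genes fell, also adjusted over the list alone and under each scaling except RLE, where 16 did. They included MYC, the kinase SGK1 (-0.59) and the transcription factors EGR3 (-0.59) and KLF6 (-0.70) (camera adjusted p = 0.000544 and adjusted p = 0.418 with an estimated correlation). Of 19 ERK output genes 16 fell and 1, the transcription factor ETV4 (0.24), rose, with the same counts adjusted over the list alone. The feedback regulators SPRED1 (-0.48) and SPRED2 (-0.45) were among those that fell (camera adjusted p = 0.000363 and adjusted p = 0.376 with an estimated correlation). ETV4 did not rise with total counts, where 18 of the ERK genes fell and 0 rose.

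Ribosomal protein mRNAs rose within labelled RNA, 74 of 79 also adjusted over the list alone, but with glycolytic mRNAs held constant 43 fell and 0 rose, and scaled to the row without a gene 79 fell. RPS4X (0.44, SE 0.03) and RPL5 (0.41, SE 0.03) were examples (camera adjusted p = 2.31e-15 and adjusted p = 0.418 with an estimated correlation). Nuclear OXPHOS genes rose in 27 of 30 cases (28 adjusted over the list alone), and 16 and 26 fell under those scalings. ATP5F1B of the ATP synthase rose by 0.44 and SDHB of complex II by 0.39 log2 per hour (camera adjusted p = 1.71e-09 and adjusted p = 0.376 with an estimated correlation). Glycolysis genes rose in 14 of 16 cases, also adjusted over the list alone, with 6 and 16 falling under the same scalings. With glycolytic mRNAs held constant, the rise of this list is lost by construction. TPI1 (0.53) and PGK1 (0.47) were examples (camera adjusted p = 2.52e-12 and adjusted p = 0.376 with an estimated correlation). Of 20 interferon response genes 11 rose and 3 fell, with the same counts adjusted over the list alone, and 11 and 18 fell under those scalings. The antiviral IFITM3 (0.49) and OAS3 (0.30) rose (camera adjusted p = 0.0344 and adjusted p = 0.376 with an estimated correlation). Beside these groups the share of counts from the mitochondrial ribosomal RNA MT-RNR2 rose over the chase, from 7.71% to 26.9% in A375 and from 7.38% to 26.4% in the MIR211 line.

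**Figure D2:**
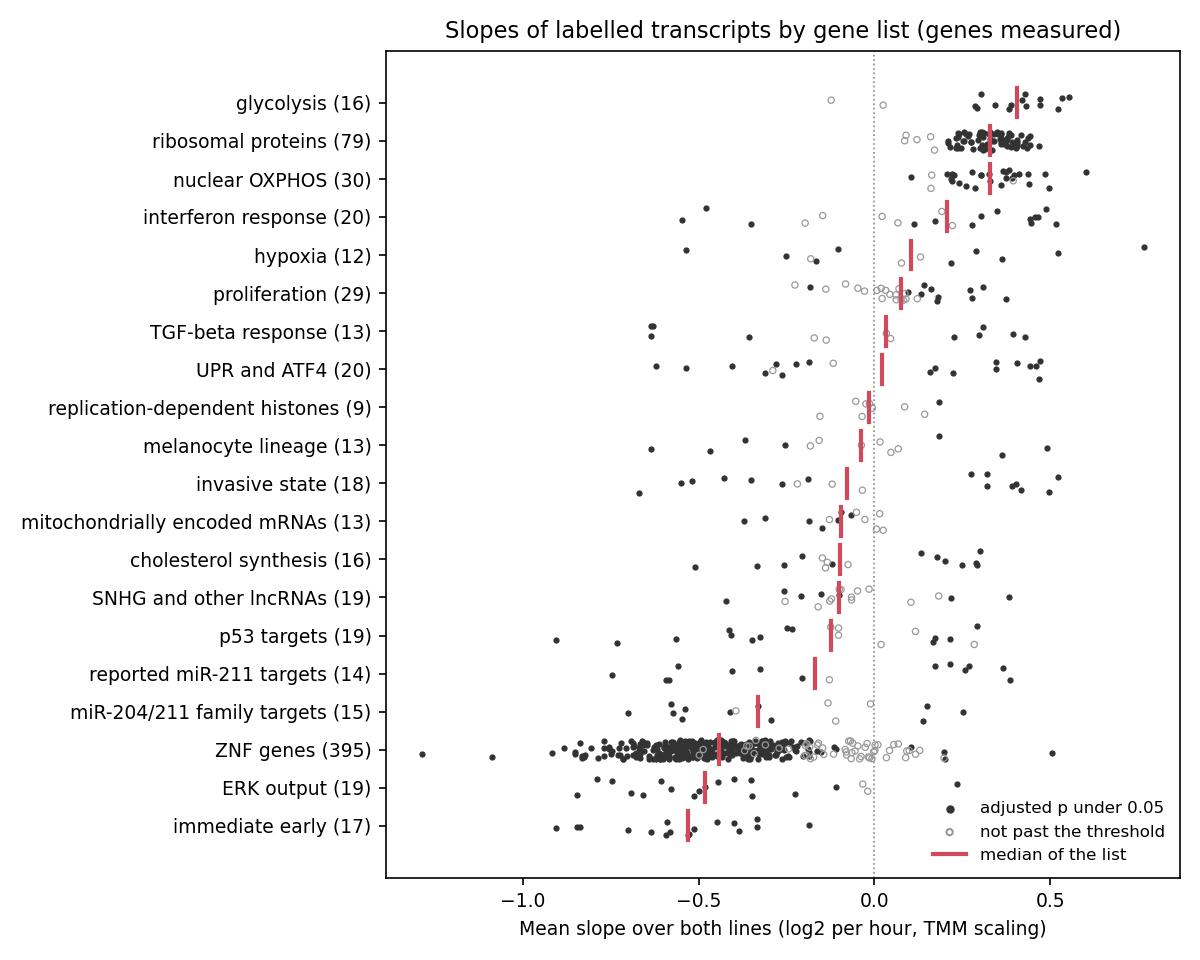
Mean slope over both lines (log2 per hour, TMM scaling) of each measured gene of the lists with at least 3 genes, where filled points passed the threshold and red bars are list medians. Immediate early, ERK output and ZNF genes lie below 0, with medians of -0.53, -0.48 and -0.44, and glycolysis, ribosomal protein and nuclear OXPHOS genes lie above it (0.40, 0.33 and 0.33), which flips to -0.06, -0.13 and -0.14 with glycolytic mRNAs held constant. For the glycolysis list the rise is lost there by construction.

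Other lists had values on both sides of 0 in the mean slope, and with glycolytic mRNAs held constant each of their rising counts was 0. Reported miR-211 targets split into 6 rising and 7 falling, the same adjusted over the list alone. IGF2R (0.36), IGFBP5 (0.39), SERINC3 (0.27), KCNMA1 (0.26), AP1S2 (0.22) and EDEM1 (0.17) rose. DUSP6 (-0.75), PDK4 (-0.59), TGFBR2 (-0.58), POU3F2 (-0.56), SOX11 (-0.41), RAB22A (-0.33) and NUAK1 (-0.21) fell. DUSP3 fell (-0.26, SE 0.08, edgeR adjusted p = 0.015). Without the 6 h library of A375 or of the MIR211 line the calls of DUSP3 (-0.25 and -0.20) and of NUAK1 (-0.20 and -0.13) were lost. The counts of rising and falling genes were 3 and 8 for 15 miR-204 and miR-211 family targets, 3 and 4 for 13 melanocyte genes, 8 and 7 for 18 invasive state genes, and 4 and 9 for 19 p53 targets, the same adjusted over the list alone. They were 5 and 4 for 13 TGF-beta response genes (5 and 5 adjusted over the list alone), 10 and 1 for 29 proliferation genes (7 and 0) and 0 and 7 for 13 mitochondrially encoded mRNAs (0 and 6). They were 2 and 5 for 19 SNHG and other lncRNAs (2 and 4) and 7 and 5 for 16 cholesterol synthesis genes (7 and 6). Examples are the sterol regulator SREBF2 (0.30, rising), the p53 target SESN1 (-0.73, falling), the chaperone HYOU1 (0.47, rising) and the melanocyte factor PAX3 (-0.63, falling). The UPR and ATF4 list (10 and 8 of 20) and the hypoxia list (5 and 4 of 12) kept their counts adjusted over the list alone, and of 9 histones 1 rose and 0 did adjusted over the list alone. Camera called none of these lists. Fry called p53 targets (adjusted p = 0.000245), UPR and ATF4 (adjusted p = 0.00103) and hypoxia (adjusted p = 0.0021). It also called family targets and the invasive state (adjusted p = 0.00277 each), and TGF-beta response, mitochondrially encoded mRNAs and proliferation (adjusted p = 0.0361, 0.0415 and 0.0482). Median and camera direction differed in sign for the reported targets (-0.17, up), the invasive state (-0.08, up) and cholesterol synthesis (-0.10, up). Median and mean did for TGF-beta response (0.03 and -0.06) and histones (-0.01 and 0.01). Among markers of other cell types, LUM (0.48) and LYZ (0.47) rose and KRT10 (-0.08), KDR (-0.03) and PDGFRB (0.09) did not pass.

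Whether decay differed between the lines was tested as the difference of slopes, MIR211 line minus A375. HMGA2, an architectural chromatin protein expressed in embryos and tumours (ENSG00000149948, chromosome 12, 65824460 to 65966291), had the smallest p. Its labelled RNA stood at 522, 386, 264 and 129 CPM at 0, 1, 3 and 6 h in the MIR211 line and at 291, 298, 384 and 342 CPM in A375. The ratio between lines went from 1.79 (95% interval 1.66 to 1.94) to 0.377 (0.341 to 0.416). The slope difference was -0.38 log2 per hour (SE 0.05, edgeR adjusted p = 1), with slopes of 0.05 in A375 and -0.33 in the MIR211 line. It passed adjusted over the list alone (adjusted p = 0.00185), as 1 of 15 miR-204 and miR-211 family targets, and has 2 seed 7mers in its 3' UTR. DUSP3 had a slope difference of -0.20 (SE 0.14), with ratios between the lines of 1.29, 1.29, 0.387 and 0.711 at 0, 1, 3 and 6 h. PDK4 had one of -0.15 (SE 0.16), and neither passed. EDEM1, with 0.15 (SE 0.05), lay on the other side of 0, and the other reported targets lay between -0.24 and 0.08.

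No gene passed the test of the slope difference by edgeR (0 of 13703, smallest adjusted p = 1), with 527 at an unadjusted p under the threshold (261 above and 266 below 0), while DESeq2 called 14. Apart from HMGA2 the smallest p at an average log2 CPM of at least 5 belonged, below 0, to RAN (-0.39), HMGB2 (-0.31), CBFB (-0.71) and PARPBP (-0.31). Above 0 they belonged to PAPPA (0.49), GLIPR1 (0.65), LRP8 (0.37), ITGB8 (0.33) and ZNF208 (0.36), none of which passed. Seed 7mers occur on both sides, with 2 in the 3' UTR of GLIPR1 and 1 in that of LRP8 above 0 and 1 in that of CBFB below 0. DESeq2 called HMGA2 and GLIPR1 (adjusted p = 7.18e-05 each), PAPPA, LRP8, ITGB8 and CBFB among these, 11 of its 14 being above 0. BTG1 (1.48) and LAPTM4B (0.71), named for their mean slopes, were also among its 14. Of the 20 lists tested none passed by camera or fry, and no list but the family targets had a member that passed adjusted over the list alone. Median and mean differed in sign for the reported targets (0.004 and -0.01), the family targets, TGF-beta response and nuclear OXPHOS. A slope difference of 3 log2 units over 6 h was recovered for 42% of simulated genes and one of 1 unit for 1%. All simulated genes had the same dispersion (0.0841). At that spread the edgeR test would miss most differences of these sizes or smaller. Genes with a smaller spread, such as IGF2R (SE 0.049), are not described by these shares.

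**Figure D3:**
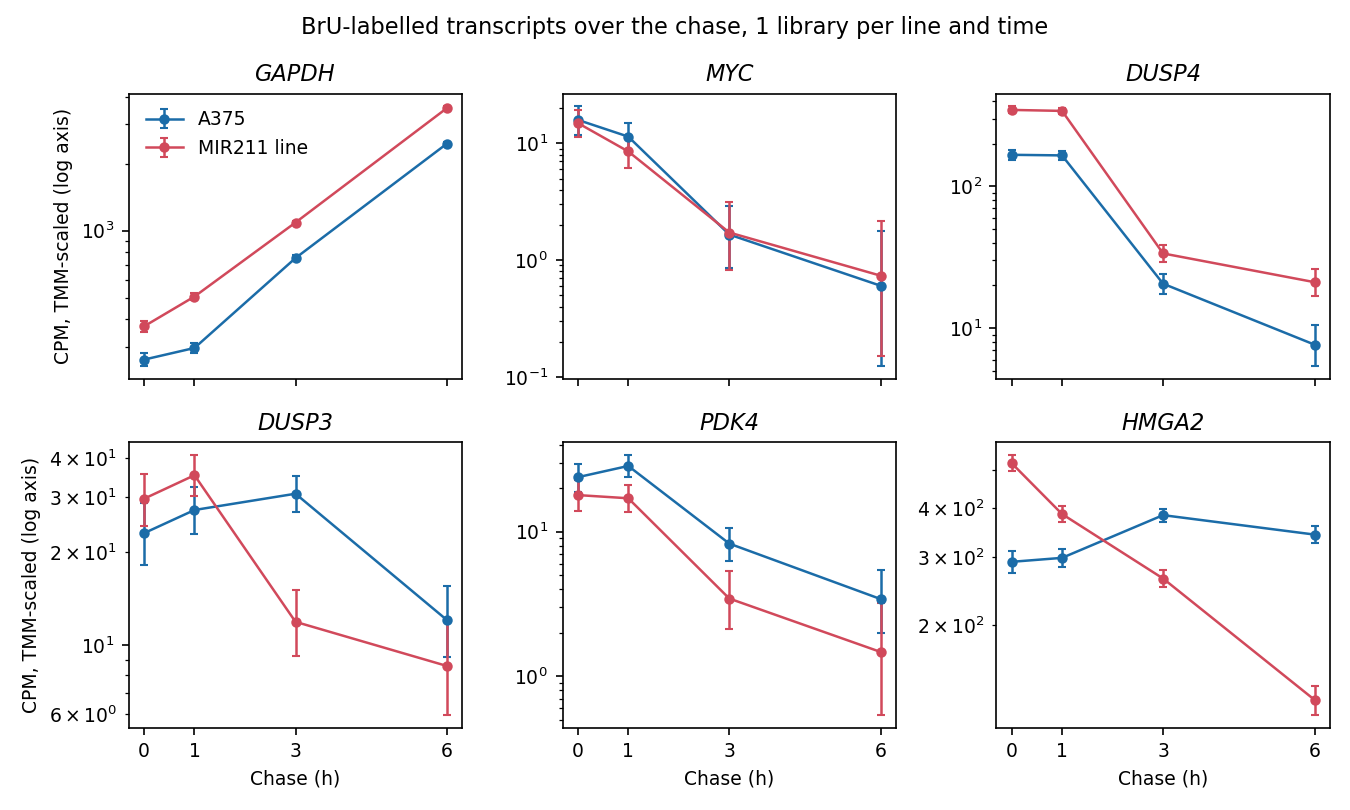
CPM (TMM-scaled, log axis) of 6 labelled transcripts against hours of chase in A375 and the MIR211 line, 1 library per point, with exact Poisson 95% intervals that cover counting error only. GAPDH rises within labelled RNA in both lines, though not when scaled to the row without a gene (slope -0.13), MYC, DUSP4 and PDK4 fall in both, and HMGA2 goes from 522 to 129 CPM in the MIR211 line while it goes from 291 to 342 CPM in A375.

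With each time matched, labelled PTGS2, IL24 and C3 were higher and COL11A1 and GDF15 lower in the MIR211 line. PTGS2, the inducible cyclooxygenase, was higher in the MIR211 line at 4 of 4 times (4.02 ± 2.29 to 241 ± 106 CPM, SD over n = 4 times, log2 5.93, SE 0.12, edgeR adjusted p = 1.24e-05). IL24 (0.393 ± 0.461 to 97.8 ± 28.1 CPM), the complement component C3 (2.2 ± 2 to 250 ± 228 CPM), the lysosomal protease CTSS (log2 7.20) and TGM2 (log2 5.99) were also higher, as were the proteases TMPRSS15 (log2 9.41) and TRHDE (log2 7.20). ARHGAP29 was higher too (log2 7.23). FDCSP had 0 counts in A375 and 1980 in the MIR211 line, at least 722-fold higher, and TUBAP13 (log2 6.43) is a pseudogene with uncertain reads. COL11A1 (361 ± 239 to 1.94 ± 1.91 CPM, log2 -7.46), the stress cytokine GDF15 (144 ± 113 to 1.63 ± 0.241 CPM, log2 -6.20) and the growth factor binding protein IGFBP5 (82.6 ± 57.1 to 6.82 ± 5.45 CPM) were lower at each time. So were HKDC1, a hexokinase (log2 -5.56), the neuronal adhesion molecule NRCAM (log2 -4.77), the lipid phosphatase INPP5D (log2 -4.61), the diacylglycerol kinase DGKI (log2 -4.57), neurotensin NTS (log2 -4.16), the lipid transporter ABCA12 (log2 -3.84) and the transcription factor TFAP2B (log2 -3.72).

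In all, 3546 of 13703 genes passed for the line difference, 1864 higher and 1682 lower in the MIR211 line (47.4% lower). Glycolytic mRNAs held constant moved the median by -0.463 and gave 6444 genes (87.3% lower). The row without a gene moved it by -0.197 (2650 genes, 65.2% lower), and total counts moved it by -0.106 (3606 genes, 58.6% lower). Single libraries mattered too, since leaving out the 1 h or 3 h library gave 1965 and 1872 genes for A375 and 1870 and 1739 for the MIR211 line.

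Genes of the invasive state were mostly higher in the labelled RNA of the MIR211 line, 11 of 18 against 2 lower (12 and 2 adjusted over the list alone), and more were higher than lower under each scaling. The matrix protein SPARC (log2 2.80, SE 0.06), MMP2 (log2 5.00), the receptor kinase AXL (log2 2.21) and the activin subunit INHBA (log2 2.90) were higher, while fibronectin FN1 (log2 -1.75) was lower (camera adjusted p = 3.22e-09 and adjusted p = 0.124 with an estimated correlation). Interferon response genes were higher in 9 of 20 cases and lower in 0 (12 and 0 adjusted over the list alone), and 0 were lower under each scaling. Among them were OAS3 (log2 1.40), the RNA sensor IFIH1 (log2 2.08) and the antigen-presenting HLA-B (log2 1.15) (camera adjusted p = 4.61e-05 and adjusted p = 0.221 with an estimated correlation). Of 19 p53 targets 10 were lower and 0 higher (12 and 0 adjusted over the list alone), and 0 were higher under each scaling. Among them were TP53I3 (log2 -2.25), GDF15, the ubiquitin ligase MDM2 (log2 -1.17) and RRM2B (log2 -1.41) (camera adjusted p = 0.000243 and adjusted p = 0.207 with an estimated correlation). In RNA-seq, by contrast, MDM2 (61 ± 23.1 CPM in A375 and 75.6 ± 17.3 CPM in the MIR211 line, n = 2) and RRM2B (53 ± 16.4 and 60.7 ± 3.59 CPM) were not lower, and neither passed. Of 16 cholesterol synthesis genes 7 were lower and 1 higher (9 and 1 adjusted over the list alone), with more lower than higher under each scaling. HMGCS1 (log2 -1.16), IDI1 (log2 -1.04) and SQLE (log2 -1.13) were lower (camera adjusted p = 0.0182 and adjusted p = 0.263 with an estimated correlation). Markers of other cell types were higher beside these groups. They were LUM of fibroblasts (1.88 ± 2.4 to 63 ± 48.1 CPM, n = 4 times), LYZ of leukocytes (3.69 ± 2.69 to 21 ± 21.1 CPM) and KDR of endothelium (1.63 ± 1.2 to 36.1 ± 8.37 CPM). PDGFRB (log2 1.76) passed adjusted over the list alone and the keratinocyte marker KRT10 (log2 -0.19) did not pass.

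Glycolysis genes were higher in 8 of 16 cases and lower in 1 (the same adjusted over the list alone), which by construction did not hold with glycolytic mRNAs held constant (2 higher, 3 lower). PFKM (log2 0.98) and GAPDH (log2 0.58) were higher (camera adjusted p = 0.0195 and adjusted p = 0.522 with an estimated correlation). Of 9 histones 2 were lower (6 adjusted over the list alone), H1-3 (log2 -1.73) and H2AC6, which had 0 counts in the MIR211 line and between 19 and 56 per library in A375 (camera adjusted p = 0.0195 and adjusted p = 0.522 with an estimated correlation). Of 395 ZNF genes 51 were lower and 11 higher (25 and 8 adjusted over the list alone), for example ZNF853 (log2 -2.90) and ZNF680 (log2 -1.04) (camera adjusted p = 0.0282 and adjusted p = 0.522 with an estimated correlation). More histones and ZNF genes were lower than higher under each scaling. By fry neither of these lists passed (adjusted p = 0.0673 and 0.0768). Of the reported miR-211 targets 3 were higher, NUAK1 (log2 2.31), AP1S2 (log2 1.81) and TGFBR2 (19.8 to 48.4 CPM), with the same counts adjusted over the list alone, and 5 were lower. These were IGFBP5 (log2 -3.64), the transcription factor SOX11 (log2 -2.57), KCNMA1 (log2 -0.85), PDK4 (log2 -0.83) and SERINC3 (log2 -0.32). The call of SERINC3 was lost without any 1 of the 8 libraries (log2 -0.39 to -0.22). Those of PDK4 (log2 -0.88 to -0.61) and KCNMA1 (log2 -0.92 to -0.81) were lost without any 1 of the 6 libraries at 1, 3 or 6 h. DUSP3 did not pass (log2 -0.26, SE 0.32, adjusted p = 0.59). As a list the reported targets passed by fry (adjusted p = 0.0183) but not by camera (adjusted p = 0.364).

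The other lists went both ways in the line difference and were not called by camera. Fry called nuclear OXPHOS (adjusted p = 0.000605), hypoxia (adjusted p = 0.0019) and the melanocyte lineage (adjusted p = 0.00637). It also called UPR and ATF4 (adjusted p = 0.0201), proliferation (adjusted p = 0.039) and TGF-beta response (adjusted p = 0.0422), but not the rest of these lists. Higher and lower counts were 4 and 5 for 15 miR-204 and miR-211 family targets, 2 and 5 for 29 proliferation genes and 2 and 3 for 17 immediate early genes, the same adjusted over the list alone. They were 4 and 2 for 19 SNHG and other lncRNAs, 2 and 1 for 20 UPR and ATF4 genes and 4 and 1 for 12 hypoxia genes, the same adjusted over the list alone. They were 5 and 4 for 19 ERK output genes (6 and 6 adjusted over the list alone), 4 and 2 for 13 melanocyte genes (5 and 3) and 2 and 3 for 13 TGF-beta response genes (3 and 4). They were 9 and 8 for 79 ribosomal proteins (7 and 3), 1 and 4 for 13 mitochondrially encoded mRNAs (2 and 4) and 4 and 1 for 30 nuclear OXPHOS genes (2 and 1). Single members with large values were the chemokine CXCL8 (log2 5.61), the cystine transporter SLC7A11 (log2 4.66), the matrix proteins TGFBI (log2 3.68) and THBS1 (log2 3.57), the melanin enzyme DCT (log2 2.05) and the lysyl oxidase LOXL2 (log2 1.97) on the higher side. On the lower side were ID3 (log2 -2.96), the replication clamp PCNA (log2 -1.67) and SOX10 (log2 -1.49). Median and mean differed in sign for ERK output (-0.13 and 0.02), and median and camera direction for TGF-beta response (-0.13, up). With glycolytic mRNAs held constant all of these lists had more genes lower than higher. The higher and lower counts were then 0 and 48 for ribosomal proteins, 0 and 22 for proliferation, 0 and 9 for mitochondrially encoded mRNAs, 1 and 9 for nuclear OXPHOS and 1 and 6 for family targets. They were 4 and 7 for ERK output, 3 and 5 for the melanocyte lineage, 2 and 7 for TGF-beta response and 1 and 5 for immediate early genes. They were 2 and 6 for UPR and ATF4, 2 and 4 for SNHG and other lncRNAs and 1 and 2 for hypoxia.

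The line differences seen by RNA-seq and by BRIC-seq were correlated across 12677 genes (Pearson 0.408, Spearman 0.245, genes not being independent replicates). The assays differed in RNA composition. Mitochondrially encoded RNA made up 0.547% to 0.82% of RNA-seq counts and 18.1% to 34.1% of BRIC-seq counts, and small noncoding RNA 12.4% to 14.2% and 0.0547% to 0.255%. Replication-dependent histones measured were 46 in RNA-seq and 9 in BRIC-seq. Of the 73 genes called in RNA-seq, 33 were measured in both assays, and 30 of these had the same sign in BRIC-seq. Both assays called 19 genes higher, where independent lists would share 2.92, and 4 lower, where they would share 1.53, and 2 had opposite calls. Of the BRIC-called genes, 2237 of 3380 (66.2%) had the same sign in RNA-seq. IL24, TGM2, FDCSP and TUBAP13 were among the 10 named rises of both assays, and COL11A1 among the 10 named falls of both. Other named genes of labelled RNA had RNA-seq means (n = 2) that went the same way, PTGS2 (3.58 to 63.3 CPM) and TRHDE (4.84 to 46.4 CPM) upward. GDF15 (197 to 11 CPM), HKDC1 (128 to 19.3 CPM) and IGFBP5 (60.1 to 9.66 CPM) went downward. Of other named rises in labelled RNA, TMPRSS15 (66.4 ± 8.14 CPM in A375 and 81.1 ± 24.4 CPM in the MIR211 line) and C3 (54.3 ± 34.7 and 85.9 ± 42.9 CPM) differed little in RNA-seq (n = 2), and neither passed there. ARHGAP29, also a named rise in labelled RNA, was at 7.53 ± 0.571 CPM in A375 and 13 ± 7.53 CPM in the MIR211 line in RNA-seq. Some genes lower in labelled RNA were not lower in RNA-seq. There NTS was at 4.45 ± 0.798 CPM in A375 and 25.2 ± 12.4 CPM in the MIR211 line, and TFAP2B at 49.9 ± 7.72 and 69.3 ± 12 CPM (n = 2). NRCAM (46.6 ± 9.41 and 43.8 ± 3.89 CPM) and DGKI (83.3 ± 35.1 and 73.3 ± 14.3 CPM) differed little in RNA-seq, and none of these 4 passed there. ABCA12 (0 and 0.0884 ± 0.125 CPM) and INPP5D (0.191 ± 0.271 and 0.296 ± 0.085 CPM) were barely seen in RNA-seq of either line. In labelled RNA their average log2 CPM was 5.23 and 5. BIRC7 and KRT75, which fell in RNA-seq, had 0 BRIC-seq counts in all 8 libraries. In labelled RNA, UTS2 was at 1.77 ± 0.85 CPM in A375 and 1.6 ± 0.294 CPM in the MIR211 line, and GLDC at 9.87 ± 4.41 and 8.21 ± 3.32 CPM (n = 4 times). ATP6V0D2, which fell in RNA-seq, had more labelled RNA in the MIR211 line (0.221 ± 0.442 to 8.38 ± 4.02 CPM). The RNA-seq change and the slope difference had correlations of 0.026 (Pearson) and 0.024 (Spearman).

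Genes with a miR-211 seed site were not shown to differ in a way particular to that site in these comparisons. In RNA-seq the 2771 genes with the 7mer AAAGGGA in the 3' UTR had a mean log2 change -0.025 away from that of 10550 others, although their median was slightly higher (0.008 against 0.0048). That shift ranked 5 from the most negative among the 35 7mers of the same base composition (1 to 27 when genes were resampled). The shift of 1293 genes with the 8mer was -0.08. In the slope difference the 2431 genes with the 7mer lay 0.0153 log2 per hour above 8325 others (rank 20, resampled 4 to 34). In the line difference they lay 0.0605 above (rank 8, resampled 1 to 28). The resampled intervals of the shifts in the slope difference (0.0073 to 0.0231) and line difference (0.0109 to 0.1127) lay above 0, opposite to repression. The other 7mers of the same composition were all shifted above 0 there too (lowest 0.0047 and 0.0426), so these shifts are not particular to the miR-211 site. Among those 7mers, AAGGGAA is itself part of the 8mer.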

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

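Of the tests in this part, both tests of the row that names no gene, scaling to that row, and the test for too few DUSP3 reads were chosen after the result was seen; the test for a general difference between cultures was not.

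The BRIC-seq table ends with 1 row that names no gene, a signal that no comparison was built on. Its counts were 3, 9, 31 and 80 at 0, 1, 3 and 6 h in A375 and 3, 10, 36 and 81 in the MIR211 line. Deeper libraries at later times do not account for this rise, because the CPM went up 9.82-fold in A375 and 11.3-fold in the MIR211 line, and the upper 95% bounds at 0 h (3.28 and 3.15) lay below the lower bounds at 6 h (8.71 and 9.65). A stable cellular RNA could rise in this way and stays open. With TMM scaling the slope of the row was 0.647 log2 per hour (SE 0.048). That lay above the level (0.512) that all but a small share of the tested genes stayed under, while 20 of 13565 genes were steeper. That the row is an added RNA of constant amount is a hypothesis that these values cannot decide.

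DUSP3 was lower in the MIR211 line by RNA-seq (ratio 0.182) but not in labelled RNA at 0 h. Too few BRIC-seq reads cannot account for this, since the 0 h ratio was 1.29 with a 95% interval of 0.956 to 1.75, which lies above the RNA-seq ratio. A general difference between the cultures of the assays may account for it and stays open. This was read in 17 other genes with a large RNA-seq change and an average log2 CPM of at least 5 in both assays. Of these, 12 (70.6%, interval 44 to 89.7) had at least 0.5 of that change at 0 h. UTS2 and GLDC, which fell in RNA-seq and differed little in labelled RNA, lay under that limit, so the share does not cover such genes. A loss of DUSP3 RNA during the chase comes after 0 h and so cannot account for the 0 h ratio. BrU was given for 24 h, however, so labelled RNA could also be lost before 0 h. Faster loss in the MIR211 line would then lower the 0 h ratio. The ratio of 1.29 does not show this, though it rests on 1 library per line. Whether miR-211 speeds the loss of DUSP3 RNA stays open, with a slope difference of -0.20 (SE 0.14) that did not pass.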

How the results depend on the processing

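Scaling to the row without a gene and leaving out mitochondrially encoded genes were chosen after the result was seen; all other alternatives were planned. Over the alternatives the values of named genes kept their direction and their side of the threshold in 265 of the RNA-seq cases, 550 of the mean slope, 413 of the slope difference and 533 of the line difference, while 74, 19, 0 and 25 lost a call, 7, 3, 6 and 1 gained one, and 13, 23, 31 and 19 changed sign. With 1 RNA-seq library left out, the lone library of that line was assumed to vary like those of the other line. By total counts BRIC-seq was shallowest at 0 h, where the smallest library held 2.67 M counts. The fewest genes above 10 counts were seen at 6 h, with 11999 in A375 and 11380 in the MIR211 line. Where no cause is given, the cause was not tested.

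For RNA-seq, DESeq2 called 748 genes and no filter 237. With the letters a and b as a replicate block 192 passed, including all 73, although the 2 pairs deviated with a correlation of only 0.238. With 1 library left out, between 0 and 15 passed, where fewer samples were fitted. For the slope difference DESeq2 called 14 genes, no filter gave 1 and time as a shared factor gave 1.

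With glycolytic mRNAs held constant, 10356 genes passed for the slope of A375, 10539 for that of the MIR211 line and 6444 for the line difference. Scaled to the row without a gene, 13394 passed for the mean slope, 12448 for A375 and 13067 for the MIR211 line. By construction, each scaling changes all genes of a library by the same factor, and so moves all slopes together. With 1 library left out, the slope of A375 gave 0 to 6770 genes, that of the MIR211 line 0 to 5870 and the line difference 1739 to 2863. For gene lists, 0 passed with an estimated correlation in RNA-seq, the mean slope, both single slopes and the line difference, and by fry 0 passed in RNA-seq, 15 in the mean slope, 12 in the slope of A375 and 12 in the line difference.

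Values that changed sign were small in RNA-seq, where RAB22A went to 0.006 with total counts, 0.005 with no filter and 0.005 with the block. In the slope difference, total counts gave RAB22A -0.024 and DUSP6 -0.027, and no filter gave -0.013 and -0.015. Rank of time gave RAB22A -0.005 and NUAK1 0.055, and a shared time factor gave NUAK1 0.005. Scaling to the row without a gene gave IGF2R -0.038, KCNMA1 -0.026, RAB22A -0.071, DUSP6 -0.079 and SOX11 -0.023.

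In the line difference, total counts gave EDEM1 -0.065 and leaving out the 0 h pair gave DUSP6 0.009. Glycolytic mRNAs held constant gave IGF2R -0.274, POU3F2 -0.349, RAB22A -0.272 and EDEM1 -0.424. Scaling to the row without a gene gave IGF2R -0.007, POU3F2 -0.048 and EDEM1 -0.157.

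In the mean slope, glycolytic mRNAs held constant gave IGF2R -0.102, KCNMA1 -0.205, AP1S2 -0.25, SERINC3 -0.194, EDEM1 -0.296 and IGFBP5 -0.079. Scaling to the row without a gene gave DDOST -0.016, ACTB -0.123, GAPDHP1 -0.117, ITM2A -0.128, GAPDH -0.13, LAPTM4B -0.13, LAMA2 -0.125, SH3BGRL -0.145, GPX3 -0.148 and TPI1 -0.146. It gave IGF2R -0.313, KCNMA1 -0.418, AP1S2 -0.465, SERINC3 -0.411, EDEM1 -0.509 and IGFBP5 -0.278.

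With 1 library left out, signs changed for the following genes. In RNA-seq the range was -0.25 to 0.228 for NFAT5, -0.151 to 0.111 for POU3F2, -0.223 to 0.238 for RAB22A, -0.07 to 0.123 for AP1S2, -0.7 to 0.186 for SERINC3 and -0.322 to 0.195 for DUSP6. In the mean slope it was -0.225 to 0.001 for NFAT5. In the slope difference it was -0.373 to 0.061 for TGFBR2, -0.464 to 0.273 for NFAT5, -0.023 to 0.048 for IGF2R, -0.537 to 0.107 for POU3F2 and -0.063 to 0.16 for KCNMA1. It was -0.27 to 0.175 for RAB22A, -0.099 to 0.185 for NUAK1, -0.583 to 1.245 for DUSP6 and -0.08 to 0.176 for SOX11. In the line difference it was -0.506 to 0.194 for DUSP3, -0.565 to 0.078 for NFAT5, -0.076 to 0.34 for POU3F2, -0.513 to 0.085 for DUSP6 and -0.122 to 0.162 for EDEM1.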

Other observations

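The tests of seed sites and of other splits in this part were set before the data were examined; the reading of the splits by whether they keep the times matched, the description of transcript classes and the remarks on HMGA2 and on genes that differ between assays were chosen after the result was seen.

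Mean slopes were also summarised by transcript class, relative to the scaled total of labelled RNA and with no test of a difference between classes. The 1246 lncRNAs had a median mean slope of -0.23 log2 per hour, with 134 rising and 629 falling, and the 10809 protein-coding genes one of -0.02, with 3362 rising and 3537 falling. The nuclear lncRNA MALAT1 rose (0.38) and the imprinted antisense RNA KCNQ1OT1 fell (-0.42). The 1313 pseudogenes had a median of 0.08, with 554 rising and 363 falling, and reads that are uncertain. The classes overlapped, with quartiles of -0.44 and -0.01 for lncRNAs and of -0.25 and 0.20 for protein-coding genes. Under glycolytic mRNAs held constant the median of all genes moved by -0.464, so these signs are relative.

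The line differences of PMEL and MITF were unlike in RNA-seq and labelled RNA, PMEL in sign and MITF in size, though a difference between the assays was not tested. PMEL, a melanosome protein, had a log2 value of -1.51 in RNA-seq and 2.56 in BRIC-seq, and both values passed adjusted over the list alone in their comparison. MITF was at 41.6 ± 17.5 CPM in A375 and 29.6 ± 22.8 CPM in the MIR211 line in labelled RNA (n = 4 times), against a log2 change of -2.50 in RNA-seq.

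Repression through miR-211 seed sites may be too small to see in these libraries. If it acted widely, genes with the 7mer would rank lowest among 35 7mers of the same composition. They ranked 5 in RNA-seq, 8 in the line difference and 20 in the slope difference, with resampled ranks of 1 to 27, 1 to 28 and 4 to 34. These intervals are too wide to decide it in any of the 3 comparisons.

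Among the 32 splits of the BRIC-seq libraries that could be fitted, 1 gave as many calls for the line difference as the real one (3546 genes), which is the real split, and the highest of the others gave 0. Only 8 splits keep 1 library of each time on both sides, as the matched design needs, and the highest of the others among these also gave 0. These 8 are too few for a share under 0.05. The slope difference gave 0 genes in the real split by edgeR (527 at an unadjusted p under the threshold, 14 by DESeq2) and at most 0 in the other splits. With a real count of 0 all 35 splits are as large by definition, so they say nothing about chance.

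HMGA2, a family target with 2 seed 7mers, had more labelled RNA in the MIR211 line than in A375 at 0 h (ratio 1.79) and less at 6 h (0.377). DESeq2 (14 genes called) called its slope difference and edgeR did not. In RNA-seq its log2 change was -0.67 (SE 0.49), which did not pass. GLIPR1, which also has 2 seed 7mers, had a slope difference of 0.65 on the other side of 0, which DESeq2 called and edgeR did not. No explanation of these values was tested.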
